A study of Mus musculus with 2 samples.

How the data were processed

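CD8-enriched spleen cells were profiled by droplet single-cell RNA sequencing with 3′ end counting, in 1 library labelled control (wild-type C57BL/6) and 1 labelled IL-4 knockout (strain B6.129P2-Il4tm1Cgn/J). Per the labels, the mice were male and 6 to 8 weeks old, and cells were enriched with CD8 MicroBeads. How many mice went into each library, and which part of Il4 the allele alters, is not given in the sources used here.

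The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode. They were made with Cell Ranger 5.0.0, per the file headers, on genome build mm10, per the submitters' processing notes. Those notes also list Seurat 4.3.0, whose role is not given in the sources used here. Each matrix was present in 2 copies with 0 differing entries, and 1 copy was used. The depth was 64339006 UMIs over 11370 barcodes in the library labelled control and 78847813 UMIs over 11561 barcodes in the library labelled IL-4 knockout, with 32285 genes in each. Gene positions came from the GENCODE M21 annotation of mm10, which matched 32235 of the gene identifiers (99.8%).

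Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. Doublets were scored within each library by Scrublet, as run by scanpy, with an expected rate of 8%. Its automatic threshold called 462 barcodes in the library labelled control and 0 in the library labelled IL-4 knockout, where it had not worked. The threshold of the library labelled control, 0.366, was therefore used for both, a choice made after seeing the data, and it removed 462 barcodes (4.06%) and 325 barcodes (2.81%). The filters left 9433 of 11370 barcodes (83.0%) and 10777 of 11561 (93.2%).

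Kept cells of both libraries were clustered together after scaling each cell to 10000 UMIs and taking logs, with 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. TCR and immunoglobulin segments, mitochondrial and ribosomal protein genes, Y-linked genes, Xist and most of the compared gene lists were held out of the highly variable genes. The lists for cytotoxic genes, chemokines and homing, NK receptors and proliferation were not held out. Clusters were named from 18 marker lists, using the 20 genes with the largest fold against all other cells (5 CPM added to each side) among those in at least 10% of the cluster's cells, at 30 CPM or more and at a log2 fold of at least 0.5. A name needed at least 3 of its markers there. The naive name needed at least 6 naive markers at 50% or more of their median over T clusters, and at most 1 leading marker each of virtual memory, antigen-experienced, CD4 and gamma delta T cells. The markers were fixed in advance, whereas these naming steps were written once the files were at hand. A cluster of shallow cells with none of its markers among its top 10 genes stayed unnamed. That last step was added after the clusters had been seen, because cluster 18, led by Lyz2, had been named naive-like, and it took cluster 18 out of the CD8 T-like cells. CD8 T-like cells are the T clusters with fewer than 2 leading markers of any single non-T class, or with at least 3 virtual memory markers, that were not left out by that step, namely clusters 0 to 3, 5 to 7, 12, 13, 16 and 21. CD4 T cell markers did not exclude a cluster, and cluster 12 had 2 of them among its leading genes (Ikzf2 and Izumo1r) and cluster 21 had Cd4 with the thymocyte genes Rag1 and Dntt.

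A check of the top 10 genes found more markers of another class than of the own class in clusters 0, 2 and 19. Cluster 0 had 1 marker of plasmacytoid dendritic cells, Ccr9, which CD8 T cells also express, and none of the naive list. Cluster 2 had 3 interferon-response markers (Ifit3, Ifit1, Isg15) against 1 naive marker, and cluster 19 had 3 proliferation markers against 1 marker of type 1 dendritic cells. These clusters are therefore given by number. Cluster 17 met the marker rule for neutrophils with 3 markers, but its top 10 genes also hold monocyte genes such as Lyz2, Fn1 and Ccr2, so it is called by its number, a choice made after seeing the data. Values pooled over clusters 0 to 3, called naive-like for short, describe those clusters together, with the values of each beside them, and the pooled type 1 dendritic-like cells include cluster 19 unless stated otherwise.

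With 1 library per group there is no test, p-value or standard error. Raw UMIs were summed over the cells of a class per library and given as CPM. The log2 ratio, labelled IL-4 knockout over labelled control, has an exact conditional binomial 95% interval, CPM values have exact Poisson 95% intervals and shares exact Clopper-Pearson ones. All of them cover counting error only. Where a count of Il4 UMIs, or of cells with a UMI or in the gate, was 0, the level that 3 counts would give is stated. The median log2 ratio over genes with a mean of at least 50 CPM was 0.11 in virtual memory-like cells and -0.04 in clusters 0 to 3, and log2 ratios between the libraries are given relative to that median unless stated otherwise. In virtual memory-like cells the median moved to 0.08 with edgeR's TMM factors, to 0.21 with ribosomal protein and mitochondrial genes out of the total and to -0.03 with Gm42418 out of the total. In clusters 0 to 3 it moved to 0.14, 0.19 and -0.18.

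The named genes were set by size. In virtual memory-like cells they are the 12 with the largest and the 12 with the smallest ratio among genes with a mean of at least 50 CPM and at least 1.5-fold in either direction, and in naive-like cells the 5 largest and the 5 smallest. Immunoglobulin, TCR segment, mitochondrial, ribosomal protein, haemoglobin and Y-linked genes, Xist, unnamed gene models and markers of non-T classes were left out. In each gene list 2 to 4 members with the largest absolute ratio at 10 CPM or more could be named, and Il4, Il4ra, Eomes, Tbx21, Il2rb, Cd44, Cxcr3, Itga4 and Cd5 always. For virtual memory-like against naive-like cells the rule took the 6 held-out genes with the largest and the 4 with the smallest ratio among those at a mean of at least 50 CPM with the same direction in both libraries. Other names were chosen after their values were seen. The 14 gene lists begin with IL-4 and STAT6 response, cytokine receptors and survival, memory and naive transcription factors, and cytotoxic and effector genes. They go on with chemokines with homing and adhesion, NK receptors, TCR signalling, and inhibitory receptors and exhaustion. The last are type I interferon response, interferon gamma response, MHC class I, proliferation, immediate early and stress genes, and Il4 neighbours on chromosome 11. A list is described by the median of its members at 10 CPM or more and the percentile of that median among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Filters, clustering settings, markers, lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined.

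The alternatives were a looser filter (200 genes, 20% mitochondrial) and a stricter one (1000 genes, 5%), doublets kept, genes centred within each library before clustering, resolutions 0.5 and 2, gene lists kept in, clustering of cells thinned to 1500 UMIs, other scalings, other minimum levels, removal of cells with B cell, macrophage or erythroid UMIs, and a gate on UMIs of Il2rb with Cd44, Eomes, Tbx21 or Cxcr3. Clustering of CD8 T-like cells alone, with genes centred within each library, doublets called by the automatic thresholds, single clusters, the gate without thinning and totals without Gm42418 were added after seeing the data.

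The ratio step was tested on simulated Poisson counts, drawn for both libraries from 1 shared profile with set folds. The interval assumes the same counting error, so this checks the computation only. Spread between cells or libraries was not simulated. For virtual memory-like cells, over 2108 genes, 100% of 50 doubled and 100% of 50 halved genes passed the 1.5-fold size, 0% of those changed 1.25-fold, 2% of those changed 0.8-fold and 0% of unchanged genes, and the interval held the true ratio of 95.2% of unchanged genes. For naive-like cells, over 2106 genes, the shares were 100%, 100%, 0%, 0% and 0%, and 95.1%. A list of 15 doubled genes lay at percentile 100 in each, and of 40 unchanged lists 2.5% and 0% lay at or past the outer percentiles.

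Analyses used Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1, R 4.3.3 and edgeR 4.0.16. The labels give no batch, so the libraries and any difference in handling cannot be told apart.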

Results

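The series concerns virtual memory CD8 T cells, which carry a memory phenotype without encounter of foreign antigen, in mice with and without interleukin 4 (IL-4), a cytokine that signals through the receptor chain Il4ra and the transcription factor Stat6. Spleen cells enriched for CD8 were captured in droplets and the 3′ ends of their transcripts were counted. There was 1 library per genotype, so no difference given here has a replicate check, and the values describe these 2 libraries. The library labelled control held 11370 barcodes, with medians of 5850 UMIs and 1750 genes. The library labelled IL-4 knockout held 11561 barcodes, with medians of 6347 UMIs and 1756 genes. After filtering, 9433 and 10777 cells remained, with medians of 6283 and 6405 UMIs. Fewer than 500 genes were found in 1309 barcodes labelled control and 352 labelled IL-4 knockout, and more than 10% mitochondrial UMIs in 544 and 311. Ribosomal protein genes took a median of 32.6% of a kept cell's UMIs in the library labelled control and 42.0% in the other. Gm42418, a gene model that overlaps ribosomal RNA sequence, took 12.6% and 4.11% of all UMIs.

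Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669 in mm10), the targeted gene, went against the labels. CD8 T-like cells held 1 Il4 UMI in the library labelled control, or 0.0198 CPM (0.000501 to 0.110), and 819 UMIs in the library labelled IL-4 knockout, or 11.3 CPM (10.5 to 12.1). In naive-like clusters 0 to 3 the library labelled control held 0 Il4 UMIs, where 3 counts would be 0.0842 CPM, and the other held 743, or 12.7 CPM (11.8 to 13.7). Within each of these clusters the library labelled IL-4 knockout lay between 11.8 and 14.9 CPM, against 0 UMIs, where 3 counts would be 0.0912, 10.01, 2.93 and 2.13 CPM in clusters 0 to 3. In cluster 1, with 66 cells labelled control, the depth hardly separates the libraries, as the lower bound of the log2 ratio was 0.13. In virtual memory-like cells Il4 stood at 0.105 CPM (0.00265 to 0.584, 1 UMI) and 6.45 CPM (4.61 to 8.79, 40 UMIs). All groups are therefore called by their labels, and every direction given here rests on them. A 3′ tag outside the altered part of the gene does not check the coding sequence.

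The share of CD8 T-like cells with an Il4 UMI was 0.0143% (0.000362 to 0.0795) of 7002 cells labelled control and 7.60% (7.09 to 8.14) of 10115 cells labelled IL-4 knockout, at median depths of 6752 and 6479 UMIs. Thinned to 1500 UMIs per cell, which left out 89 and 9 cells, it was 0 of 6913 cells, where 3 cells would be 0.0434%, and 1.79% (1.54 to 2.07). B-like cells, which should lack Il4, had 0 of 196 and 0 of 139 cells with a UMI, where 3 cells would be 1.53% and 2.16%, at median depths of 4572 and 3987 UMIs. Pooled B-like, macrophage-like and type 1 dendritic-like cells (clusters 8, 15 and 19 for the last) held 0.644 CPM (0.209 to 1.503) in the library labelled control and 0.867 CPM (0.105 to 3.13) in the other. These come from 5 UMIs, all in macrophage-like cells, and 2 UMIs, both in type 1 dendritic-like cells, so the 2 values do not compare like cells. The 14 measured neighbours of Il4 on chromosome 11 had a median log2 ratio of -0.02 in clusters 0 to 3 (percentile 58.7) and -0.09 in virtual memory-like cells (percentile 35). Among them, in clusters 0 to 3, Jade2 stood at -0.86 (-0.96 to -0.75, and -1.02 to -0.63 from cluster to cluster) and Sar1b, a GTPase of vesicle export, at 0.59 (0.49 to 0.70, and 0.28 to 0.91). Kif3a, a kinesin motor subunit that lies beside Il4 (chromosome 11, 53567379 to 53601967), is named after its values were seen. It stood at 3.09 and 8.09 CPM in CD8 T-like cells, a log2 ratio of 1.39 (1.13 to 1.65) not taken relative to the median. Relative to the median it was 2.08, 2.22 and 0.73 (-0.35 to 2.08) in clusters 0, 2 and 3, and cluster 1 held 0 UMIs labelled control. In the pooled cells of those 3 non-T classes it stood at 7.86 and 3.90 CPM, or -1.01 (-2.21 to 0.01), from 61 and 9 UMIs. That pool was 1420 of 2104 cells macrophage-like in the library labelled control and 129 of 505 in the other, and in B-like, type 1 dendritic-like and macrophage-like cells taken singly Kif3a stood at -0.05, -1.03 and -0.43, each with a counting interval across 0.

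**Figure D1:**
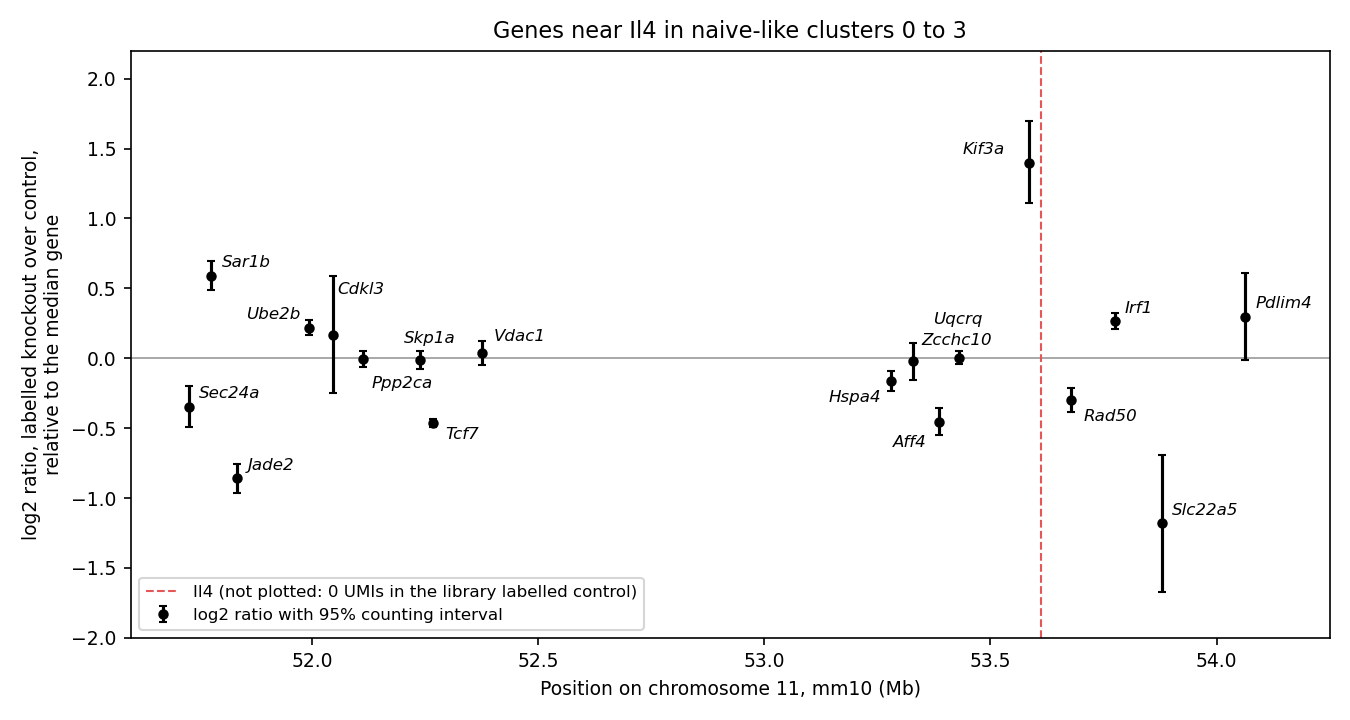
Log2 ratio of CPM, labelled IL-4 knockout over labelled control and relative to the median gene (vertical axis), against position on chromosome 11 in megabases (horizontal axis), for Il4 neighbours with at least 100 UMIs in naive-like clusters 0 to 3, with 95% counting intervals. Kif3a stands at 1.40 (1.11 to 1.70) beside the dashed line at Il4, while Rad50, on the other side of it, stands at -0.30.

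Non-T cells took a larger share of the library labelled control. Monocyte or macrophage-like clusters 4 and 11, with complement genes such as C1qc among their leading genes, made up 15.1% (14.3 to 15.8) of its kept cells and 1.20% (1.0003 to 1.42) of the library labelled IL-4 knockout. CD8 T-like cells made up 74.2% (73.3 to 75.1) and 93.9% (93.4 to 94.3). B-like cells stood at 2.08% (1.80 to 2.39) and 1.29% (1.09 to 1.52), and proliferating T-like cells, led by genes such as Mki67 and Stmn1, at 0.615% (0.467 to 0.794) and 1.16% (0.966 to 1.38).

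Of the dendritic clusters, cluster 8 (Cst3, Cxcl9 and MHC class II genes) held 387 and 203 cells, or 4.10% (3.71 to 4.52) and 1.88% (1.64 to 2.16). Cluster 15, led by Xcr1, a receptor of cross-presenting dendritic cells, held 0.721% and 0.204%, and cluster 19, led by cell cycle genes, 0.350% and 0.111%. Cluster 17, left unnamed because it has both neutrophil genes (S100a9, S100a8, Retnlg) and monocyte genes (Lyz2, Fn1, Ccr2) in the lead, held 0.307% (0.206 to 0.441) and 0.176% (0.106 to 0.275), and plasmacytoid dendritic-like cells 0.286% (0.189 to 0.416) and 0.167% (0.0990 to 0.264). T clusters with RNA of other cells, which stayed unnamed, held 1.20% and 0.232%, of which cluster 18, left out by the naming step added later, held 0.286% and 0.176%. Macrophage markers summed to 100.2 CPM in CD8 T-like cells labelled control and 19.9 CPM in those labelled IL-4 knockout, B cell markers to 402 and 289 CPM and erythroid genes to 10.7 and 20.2 CPM. These shares can be set by the CD8 bead selection, by the depth of each cell type and by the filter. With at least 1000 genes and at most 5% mitochondrial UMIs, the difference in CD8 T-like share went from 19.6 to 9.25 percentage points, and that in macrophage-like share from -13.9 to -4.49.

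**Figure D2:**
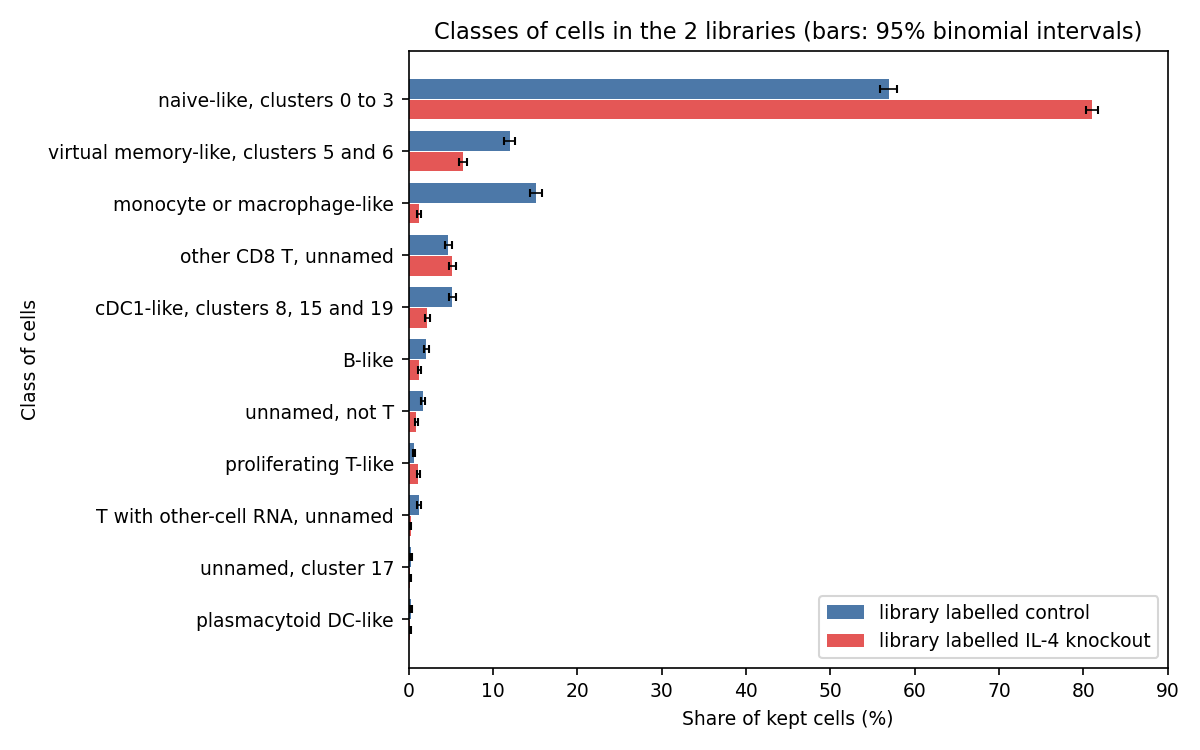
Share of kept cells in percent (horizontal axis) for each class of cells (vertical axis) in the library labelled control (blue) and the library labelled IL-4 knockout (red), with 95% binomial intervals. Monocyte or macrophage-like cells were 15.1% and 1.20%, and naive-like clusters 0 to 3 together 56.9% and 81.0%.

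Virtual memory-like cells, clusters 5 and 6, made up 16.1% (15.3 to 17.0) of CD8 T-like cells labelled control, 1129 of 7002, and 6.89% (6.40 to 7.40) of those labelled IL-4 knockout, 697 of 10115. Different clusters held most of the class in each library. Cluster 5, led by Ly6c2, Ahnak and Pde2a, had 879 cells labelled control and 68 labelled IL-4 knockout. Cluster 6, led by the chemokine Ccl5 with Ctla2a, S100a6 and S100a4, had 250 and 629. A cluster mostly of 1 library may be that library and not a cell type, and the order of the shares turned under 5 of 13 other settings, so no order is read from them. With CD8 T-like cells clustered alone, the shares were 1.94% and 1.84%.

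Levels over all CD8 T-like cells do not depend on the clusters within them. Il2rb, the receptor chain for IL-15 and IL-2, stood at 69.5 and 56.5 CPM, a log2 ratio of -0.29 (-0.36 to -0.23). Eomes, a transcription factor of memory CD8 T cells, stood at 25.1 and 18.8 CPM, or -0.41 (-0.52 to -0.30), and Cd44, an adhesion receptor used to mark memory cells, at 15.3 and 8.30 CPM, or -0.88 (-1.04 to -0.72). A Cd44 UMI was found in 8.80% and 4.53% of CD8 T-like cells, but also in 18.9% and 18.7% of B-like and 40.2% and 25.3% of type 1 dendritic-like cells, and after thinning in 2.01% and 1.03% of CD8 T-like and 5.82% and 4.48% of B-like cells. With macrophage markers also higher in CD8 T-like cells labelled control, RNA of other cells as a part of the Cd44 difference was not excluded. Il4ra stood at 48.6 and 31.7 CPM, or -0.61 (-0.69 to -0.53). On the other side, the chemokine Xcl1 stood at 11.9 and 37.6 CPM, or 1.66 (1.53 to 1.79), Ccl5 at 149.9 and 306 CPM, or 1.04 (0.999 to 1.07), and the NK receptor chain Klrd1 at 181 and 286 CPM, or 0.67 (0.63 to 0.70). Virtual memory-like cells held 20268 of the 22194 Ccl5 UMIs of CD8 T-like cells labelled IL-4 knockout. The share of CD8 T-like cells with a Ccl5 UMI was 11.7% and 10.1%, and 5.40% (4.87 to 5.95) and 5.42% (4.99 to 5.88) after thinning. It was 9.84% and 6.75% in type 1 dendritic-like cells, and 5.16% and 4.57% thinned, so nothing is read from these shares. The share of CD8 T-like cells with an Il2rb UMI was 31.6% and 27.0%, and 8.68% (8.03 to 9.37) and 7.34% (6.84 to 7.87) after thinning. In thinned B-like cells it was 0.529% (0.0134 to 2.91) and 0 of 134 cells, where 3 cells would be 2.24%. The gate on Il2rb with Cd44, Eomes, Tbx21 or Cxcr3 held 1.07% (0.841 to 1.34) and 0.752% (0.593 to 0.940) of thinned CD8 T-like cells, and 10.6% and 7.01% without thinning. In B-like cells it held 0 of 189 and 0 of 134 thinned cells, where 3 cells would be 1.59% and 2.24%, more than either CD8 T-like share. In thinned macrophage-like cells labelled control it held 5 of 769, or 0.650% (0.211 to 1.51), with 651 shallower cells left out, so the thinned CD8 T-like shares are not read as above background. Without thinning it held 0 of 196 B-like cells, where 3 cells would be 1.53%, and 0.719% of 139, 1.23% and 2.11% of type 1 dendritic-like and 1.55% and 2.33% of macrophage-like cells, which lie below the unthinned CD8 T-like shares but come from shallower cells, such as macrophage-like ones with medians of 1574 and 1795 UMIs.

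In virtual memory-like cells, the transcription factor genes Fosb, Fos, Junb and Jun, which form AP-1 and respond within minutes to stimuli, were higher in the library labelled IL-4 knockout. Junb stood at 215 CPM labelled control and 661 CPM labelled IL-4 knockout, a log2 ratio of 1.51 (1.44 to 1.59), Fosb at 1.78 (1.61 to 1.95), Fos at 1.71 (1.55 to 1.87) and Jun at 1.40 (1.29 to 1.51). Samd9l, an interferon-induced antiviral gene, stood at 17.2 and 89.6 CPM, or 2.27 (2.02 to 2.54), and Ikzf2, which encodes the transcription factor Helios, at 31.7 and 129 CPM, or 1.92 (1.73 to 2.12). Lower there were Lars2, the mitochondrial leucine tRNA synthetase, with 2051 and 564 CPM, or -1.97 (-2.02 to -1.92), Cd55, which protects cells from complement, with 82.2 and 28.9 CPM, or -1.61 (-1.86 to -1.38), and Trim56, a ubiquitin ligase of antiviral signalling, with 90.2 and 37.0 CPM, or -1.39 (-1.61 to -1.18). Gm42418, left out of the named genes as an unnamed gene model, was lower too, at -1.81 (-1.81 to -1.80). Whether the Lars2 difference is separate from that of Gm42418 was not tested.

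Most cells of the class labelled control were in cluster 5 and most of those labelled IL-4 knockout in cluster 6, so values within each cluster stand beside those of the class. In clusters 5 and 6, Junb stood at 1.82 and 1.51, Fosb at 2.71 and 0.83, Fos at 2.64 and 1.13, Jun at 1.57 and 1.23, and Samd9l at 2.86 and 2.14. Btg2, an inhibitor of cell division, stood at 1.499 in the class and at 1.39 and 1.36 in the clusters, and Coq10b, of coenzyme Q function, at 1.48, 1.74 and 1.36. Ikzf2 went from 1.92 in the class to 0.98 and 0.53. Lars2 stood at -1.69 and -1.84, Cd55 at -0.40 and -1.39 and Trim56 at -0.70 and -1.24. The chromatin gene Mllt6 stood at -1.24 (-1.47 to -1.02), and at -0.78 and -1.28 in the clusters. Ddx21, Pdk1, Mybbp1a, Fam168b, Ddx17, Dync1h1, Dgkd and Slfn8 lay between -1.07 and -0.997 in the class, from -1.39 (Fam168b) to -0.32 (Pdk1) in cluster 5 and from -1.11 (Dgkd) to -0.73 (Pdk1) in cluster 6. S100a4, S100a6, Ccl5 and Ctla2a also met the size rule, but they lead cluster 6, so their class values are not read as results. Within cluster 6 they stood at 0.97, 0.32, 0.56 and 0.19. Ikzf2 is also among the leading genes of cluster 6, and Lars2 and Cd55 among those of cluster 5.

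**Figure D3:**
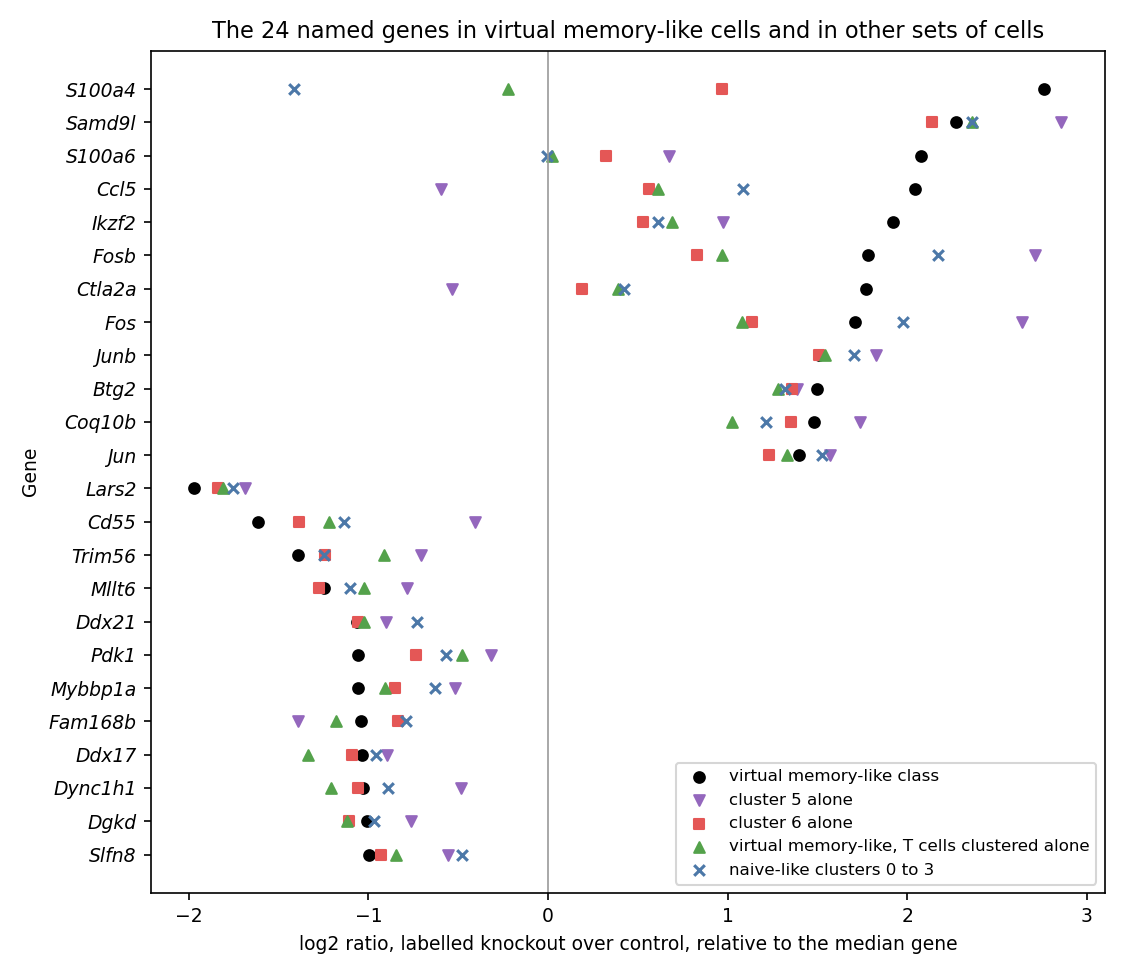
Log2 ratio of CPM, labelled IL-4 knockout over labelled control and relative to the median gene (horizontal axis), for the 24 genes named by size in virtual memory-like cells (vertical axis), in the class and in 4 other sets of cells. Junb runs from 1.51 in cluster 6 to 1.82 in cluster 5 and Jun from 1.23 to 1.57, whereas S100a6 runs from 2.08 in the class to 0.02 with T cells clustered alone and -0.00578 in naive-like cells.

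Of the genes named in advance, Il4ra stood at 58.1 and 41.1 CPM in virtual memory-like cells, a log2 ratio of -0.60 (-0.82 to -0.39), and at -0.36 (-1.04 to 0.24) and -0.78 (-1.08 to -0.48) in clusters 5 and 6. Itga4, an integrin chain low on virtual memory cells, stood at 147 and 213 CPM, or 0.43 (0.32 to 0.54), and at 0.49 and 0.55 in the clusters. Cd5, a regulator of TCR signalling, stood at -0.17 (-0.32 to -0.03), and at -0.22 and -0.29. The other genes differed between the class and its clusters. Il2rb stood at 0.21 (0.10 to 0.33) in the class but at -0.33 (-0.85 to 0.15) in cluster 5 and -0.77 (-0.91 to -0.64) in cluster 6, and Cxcr3 at 0.44 (0.25 to 0.63) but -0.39 (-1.28 to 0.38) and -0.40 (-0.63 to -0.16). Eomes was 52.2 and 54.22 CPM, or -0.05 (-0.26 to 0.15), but -0.87 (-1.12 to -0.62) in cluster 6, Tbx21 0.21 (-0.17 to 0.59) but -0.81 (-1.26 to -0.36), and Cd44 0.02 (-0.22 to 0.26) but -0.96 (-1.24 to -0.68). In cluster 5, with 68 cells labelled IL-4 knockout, these 3 stood at -0.58, -0.54 and -1.98. Il2rb, Cxcr3 and Eomes are among the leading genes by which both clusters were named. Cluster 6 also had 2 antigen-experienced markers among its top 10 genes, and an antigen-experienced-like cluster of 69 and 205 cells appeared with T cells clustered alone, where Itga4 stood at 0.34 (-0.04 to 0.72) and Il2rb at -0.42 (-0.60 to -0.25) in the virtual memory-like cells.

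Among the gene lists, immediate early and stress genes were the only list held out of the clustering that lay at percentile 100 in the virtual memory-like class as a whole. Their median was 1.01 in virtual memory-like cells, and Dusp1, a phosphatase of stress kinases, stood at 1.76 (1.52 to 2.01). It was 1.04 in cluster 5 and 0.65 in cluster 6, each at percentile 100. The type I interferon list had a median of 0.28 (percentile 99.8), with Ifit3 at 0.80 (0.48 to 1.12) and Isg15 at 0.53 (0.33 to 0.73), but -0.04 in cluster 5 (percentile 49.2) and 0.54 in cluster 6 (percentile 100). The list of inhibitory receptors and exhaustion genes had a median of 1.31 (percentile 99.99) over 4 measured members. These were Cd200 at 2.19 (1.61 to 2.80), Ctla4 at 1.995 (1.53 to 2.48), Tox at 0.63 (0.42 to 0.85) and Btla at -0.15 (-0.49 to 0.19). The list median was 0.52 and 0.43 within clusters 5 and 6 (percentiles 98.1 and 99.0), and 0.38 with T cells clustered alone (percentile 96.7).

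NK receptors (1.05, percentile 100) and cytotoxic genes (0.47, percentile 99.99) stood high in the class. Their members include Klrc1 at 2.14 (1.59 to 2.72), Gzma, a granule protease with 31.5 and 82.8 CPM, at 1.29 and Ifng at 2.81 (2.16 to 3.53). Within cluster 6 the medians were -0.01 (percentile 71.6) and 0.05 (percentile 72.4), and within cluster 5 they were 0.74 (percentile 99.5) and 0.07 (percentile 74.4). The 0.74 covers only 3 of the 8 NK receptors measured in the class. Members without UMIs in a library have no finite ratio in cluster 5 and drop out, so that median is not read. Other list medians within cluster 5 can lose members in the same way. With T cells clustered alone, NK receptors had 0.58 (percentile 99.99) and cytotoxic genes 0.03 (percentile 63.5). These lists took part in the clustering. Proliferation genes had a median of 0.38 (percentile 99.5) over 6 measured members, and 0.07 and 0.25 in clusters 5 and 6 (percentiles 73.2 and 97.1). MHC class I genes had 0.28 (percentile 94.5). The IL-4 and STAT6 list had a median of 0.10 (percentile 92.4), with members on both sides. Batf and Cebpb, transcription factors, stood at 1.06 (0.78 to 1.35) and 1.05 (0.76 to 1.35), and Myc at -0.72 (-0.98 to -0.47). In the class as a whole, medians lay nearer the middle for memory and naive transcription factors (-0.08, percentile 22.6), cytokine receptors and survival (-0.07, percentile 32.7), chemokines and homing (0.08, percentile 82.5), TCR signalling (0.09, percentile 76.6) and the interferon gamma response (-0.16, percentile 19.6). Within clusters 5 and 6 the transcription factor list lay at -0.29 and -0.26 (percentiles 0.45 and 1.35) and the interferon gamma list at 0.00459 and 0.20 (percentiles 64.8 and 99.3). Cytokine receptors and survival lay at -0.03 and -0.23 there, and chemokines and homing at -0.06 and -0.05.

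**Figure D4:**
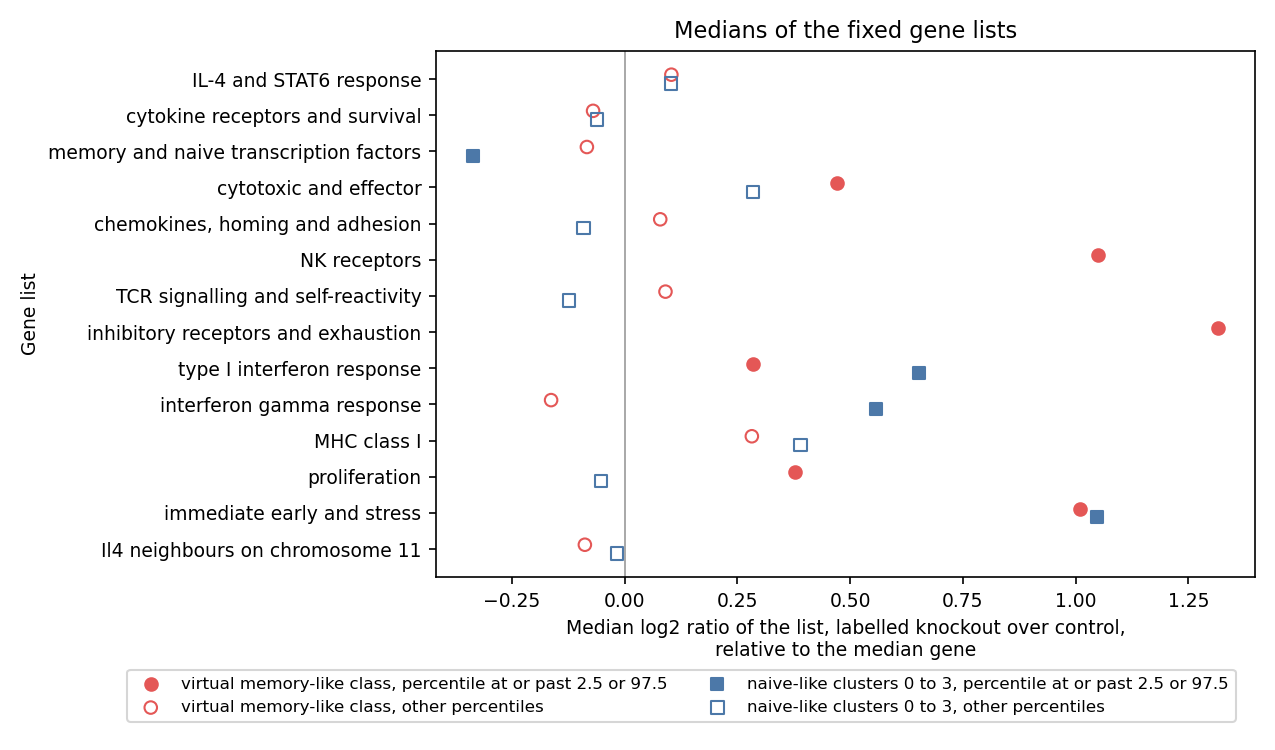
Median log2 ratio of each fixed gene list, labelled IL-4 knockout over labelled control and relative to the median gene (horizontal axis), in the virtual memory-like class (circles) and in naive-like clusters 0 to 3 (squares), with filled marks for percentiles at the outer ends. Immediate early and stress genes stand at 1.01 and 1.05, and the type I interferon list at 0.28 and 0.65.

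The comparison of naive-like cells asks which differences are not particular to virtual memory-like cells. Cluster 0 held 4905 cells labelled control and 310 labelled IL-4 knockout, and clusters 1, 2 and 3 held 66, 142 and 258 labelled control against 3039, 2958 and 2427. Values pooled over the 4 clusters are therefore followed by the range within the clusters. Ends of these ranges can rest on few UMIs, above all in cluster 1 with its 66 cells labelled control. Samd9l stood at 20.05 and 100.3 CPM, a log2 ratio of 2.36 (2.25 to 2.47) and within clusters 2.003 to 2.42. Fosb stood at 2.17 (within clusters 1.90 to 2.60), Fos at 1.98 (1.39 to 2.13) and Junb at 1.70 (1.30 to 1.79). Lower were Ctse, an aspartic protease of endosomes, with 97.7 and 5.85 CPM, or -4.03 (-4.19 to -3.86) and within clusters -4.09 to -3.39, Lars2 at -1.75 (-1.71 to -1.47), Trim56 at -1.25 (-1.40 to -0.93), Cd55 at -1.14 (-1.21 to -0.79) and Mllt6 at -1.10 (-1.15 to -0.71). Ctse was as low in virtual memory-like cells, at -4.25, where it was not among the genes named by size and is a leading gene of cluster 5.

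Plac8, which leads cluster 2, stood at 1.61 pooled but between 0.25 and 0.63 within clusters. Ctse, Lars2, Trim56, Cd55 and Mllt6 are leading genes of cluster 0. Junb is a leading gene of clusters 1 to 3, Samd9l of clusters 2 and 3, and Fos and Fosb of cluster 2. For all of these the pooled values are therefore not read alone. Those within clusters may be shifted as well by how the cells were grouped, since 90.4% to 97.9% of each cluster came from 1 library. Il4ra stood at 45.5 and 30.9 CPM, or -0.52 (-0.62 to -0.42) and within clusters -1.28 to -0.49, and Cd44, with the same limit, at 8.40 and 3.63 CPM, or -1.17 (-1.43 to -0.91) and -1.12 to -0.79 within clusters 0, 2 and 3. Cluster 1 held 0 Cd44 UMIs labelled control, where 3 counts would be 10.01 CPM, against 2.30 CPM in the other library, and gave no ratio. Il2rb stood at -0.15 (-0.24 to -0.06), within clusters -0.41 to -0.16, and Eomes at -0.45 (-0.64 to -0.27), within clusters -2.07 to -0.34. That -2.07 rests on 6 Eomes UMIs labelled IL-4 knockout in cluster 0 (-3.52 to -0.93). Cd5 stood at -0.16 (-0.23 to -0.09) but ran from -0.44 to 0.04 within clusters, and Itga4 at -0.35 (-0.39 to -0.30) but from -0.56 to 0.30. Cxcr3 was 0.24 (-0.04 to 0.53) pooled and turned within clusters, where it ran from -3.10 to -0.40. The counting interval of cluster 0 (-8.41 to -0.59, from 1 UMI labelled IL-4 knockout) lay below 0 and those of the other clusters across it. Tbx21 was -0.44 (-1.14 to 0.26), and -0.94 and -1.09 in clusters 0 and 2, each with a counting interval across 0, and clusters 1 and 3 held 0 UMIs labelled control.

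Immediate early and stress genes had a median of 1.05 in clusters 0 to 3 together and 0.88 to 1.32 within them, at percentile 100 each time. MHC class I genes, which present antigen to CD8 T cells, had 0.39 (percentile 96.6) and 0.27 to 0.39 within clusters (percentiles 94.0 to 99.7), with H2-T23 at 0.78 (0.74 to 0.82), within clusters 0.39 to 0.80. Both interferon lists stood high when pooled, type I at 0.65 and interferon gamma at 0.56, each at percentile 100. Iigp1, an interferon-induced GTPase, stood at 2.07 (1.90 to 2.23), within clusters 0.79 to 2.45. That 2.45 rests on 2 UMIs labelled control in cluster 1 (0.59 to 5.50), and clusters 0 and 3 stood at 1.68 and 1.61. Within clusters the type I list ran from -0.28 to 0.32 (percentiles 1.87 to 99.98) and the interferon gamma list from 0.03 to 0.28 (percentiles 79.8 to 99.8). The memory and naive transcription factor list had a median of -0.34 (percentile 0.29) and -0.32 to -0.02 within clusters (percentiles 0.60 to 37.9). Its member Klf2, which keeps naive T cells circulating, went the other way at 0.71 (0.69 to 0.73), within clusters 0.44 to 0.74.

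The IL-4 and STAT6 list had a median of 0.10 (percentile 93.2) and -0.09 to 0.15 within clusters, with Cebpb at 1.46 (1.31 to 1.60), within clusters 1.09 to 2.03, and Stat6 at -0.50 (-0.59 to -0.41), within clusters -0.52 to -0.08. The remaining medians were 0.28 for cytotoxic genes (percentile 94.1), -0.06 for cytokine receptors and survival (38.3), -0.09 for chemokines and homing (20.7), -0.12 for TCR signalling (8.33) and -0.05 for proliferation (63.1). Within clusters they ran from -0.16 to 0.16 (percentiles 13.1 to 80.9), -0.23 to 0.00205 (5.73 to 53.9), -0.23 to -0.01 (0.98 to 44.6), -0.10 to -0.00152 (8.38 to 41.3) and -0.18 to 0.10 (30.2 to 78.7), in that order. The NK receptor list and the list of inhibitory receptors and exhaustion genes had 2 measured members each and no median. Klrd1 stood at 0.73 (0.69 to 0.77), within clusters 0.52 to 0.82, and Btla, an inhibitory receptor, at -0.35 (-0.51 to -0.20), within clusters -1.44 to 0.07.

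Virtual memory-like cells were set against naive-like clusters 0 to 3 within each library, over genes held out of the clustering, and those named were taken among the ones with the same direction in both libraries. Of 73 such genes at the minimum level, 50 had the same direction in both, 21 higher and 29 lower, a tally of signs and not of genes that changed. Il2rb, which served to name the clusters but not to make them, stood at 48.0 CPM in naive-like and 141 CPM in virtual memory-like cells labelled control, a log2 ratio of 1.56 (1.45 to 1.66), and at 42.1 and 176 CPM in those labelled IL-4 knockout, or 2.07 (1.96 to 2.17). Hopx, a transcriptional cofactor of memory T cells, stood at 1.60 (1.45 to 1.74) and 2.08 (1.96 to 2.197), Id3, an inhibitor of E proteins, at 0.79 (0.67 to 0.90) and 1.57 (1.44 to 1.69), and Ikzf2 at 0.81 (0.61 to 1.01) and 2.26 (2.14 to 2.39). Ifngr1, an interferon gamma receptor chain, stood at 0.72 and 0.71, and Cd5 at 0.47 and 0.60. Lower in virtual memory-like cells of both libraries were Lef1, a factor of naive T cells, at -0.42 (-0.47 to -0.37) and -0.78 (-0.85 to -0.72), Satb1 at -0.33 and -0.43, Zbtb20 at -0.56 and -0.37 and Bach2, a repressor of effector genes, at -0.51 and -0.34. None of the genes lower in both libraries was past 1.5-fold in both, whereas Il2rb, Hopx, Id3, Ikzf2 and Ifngr1 were past it on the higher side. The clusters compared differ between the libraries, cluster 5 against cluster 0 for most cells labelled control and cluster 6 against clusters 1 to 3 for most of the others. Whether the ratios of the 2 libraries differ was not tested.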

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

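The tests of free RNA, of all non-T classes together, of exchanged labels, of Kif3a and of the split of the 12 named genes into 5 and 7 were chosen only after the result was seen.

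Il4 had 819 UMIs in CD8 T-like cells of the library labelled IL-4 knockout and 1 in those labelled control. Transcription from the altered allele is argued against in pooled B-like, macrophage-like and type 1 dendritic-like cells, at 0.0681 (0.00823 to 0.247) of the Il4 level in naive-like clusters 0 to 3, from 2 UMIs. It stays open over all non-T classes, at 0.364 (0.198 to 0.614), which rests on few cells. Cluster 17 held 47.9 CPM, from 9 UMIs in 5 cells, and plasmacytoid dendritic-like cells 12.4 CPM, from 2 UMIs, where 3 counts would be 18.6 CPM. Free RNA, which would reach every class alike, is argued against for CD8 T-like cells by those 3 classes, at 0.0767 (0.00928 to 0.278) of their level from 2 UMIs. All non-T classes together held 0.410 (0.223 to 0.691) of that level, which decides nothing, as 9 of their 14 Il4 UMIs lay in cluster 17. B-like cells held 0 UMIs (0 to 5.47 CPM) and macrophage-like cells 0 (0 to 8.40 CPM), against 11.3 CPM in CD8 T-like cells. In non-T cells free RNA may explain the Il4 UMIs of the 3 classes, whose ratio of Il4 to Cd8b1 was 0.666 (0.0805 to 2.41) of that in clusters 0 to 3, against 2.53 (1.37 to 4.26) over all. A few cells producing much Il4 are argued against too, as 1.10% of the Il4 UMIs lay in cells with 3 or more. In clusters 0 to 3 of that library 7.99% of cells held an Il4 UMI, against 8.12% for a Poisson draw at each cell's depth. There, 43 cells held 2 or more, against 32.4 for that draw. A larger set of cells producing little Il4 was not tested. Exchanged labels could be neither favoured nor set aside, with the IL-4 and STAT6 list at percentile 93.2 in clusters 0 to 3 but its members Il4ra (-0.52, and -1.28 to -0.49 from cluster to cluster) and Stat6 (-0.50, and -0.52 to -0.08) on the side the labels give, and a change at the altered locus stays open, since Kif3a, with a log2 ratio of 1.39 (1.13 to 1.65), was picked for its own value and so tests nothing.

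The 12 genes named as higher in virtual memory-like cells labelled IL-4 knockout, among them S100a4, Ccl5 and Junb, had a median log2 ratio of 1.77. Within cluster 6 it was 1.05, which cannot tell whether the different clusters of the 2 libraries explain it. The 5 genes not past the size rule in naive-like cells went from 2.05 in the class to 0.53 in cluster 6, as the different clusters would give. All 5 are among the leading genes of cluster 6, so their ratios may shrink there by how the cells were grouped, and the cause is not decided. Pooled over clusters 0 to 3, Ccl5 and Ikzf2 (1.09 and 0.61) missed that rule only by a level under 50 CPM. From cluster to cluster they ran from -1.74 to 0.56 and from -0.15 to 1.35. The 7 others, such as Junb, had a median of 1.36 against 1.51, which argues against that cause for them as a set, although Fosb and Fos, among them, went from 1.78 to 0.83 and from 1.71 to 1.13. In clusters 0 to 3 the 12 genes had a median of 1.27 but ran from -1.41 (S100a4) to 2.36 (Samd9l), so whether the difference is shared with those clusters stays open for the 12 as a set.

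Il2rb stood at 0.21 in virtual memory-like cells and -0.15 in clusters 0 to 3, but at -0.33 and -0.77 within clusters 5 and 6, and whether the 2 values differ was not tested. Itga4 stood at 0.43 and -0.35 (-0.56 to 0.30 from cluster to cluster), a difference that was not tested either. S100a4, which leads cluster 6, stood at 2.76 and -1.41 (-2.58 to -0.31), again without a test of the difference. Cluster 17, of unnamed myeloid cells, held Il4 in the library labelled IL-4 knockout at 47.9 CPM (21.9 to 90.8), from 9 UMIs in 5 of 19 cells, with 0 UMIs of the basophil and mast cell genes Mcpt8, Cd200r3, Gata2, Fcer1a and Cpa3, while S100a8 was found in 1 and Cd3e in 2 of those 5 cells, so which cells hold it stays open. Cluster 21 had 22 cells, all labelled IL-4 knockout, with Rag1 in 21 and Dntt in 22 of them, which are genes of thymocytes.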

How the results depend on the processing

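The tests of single clusters, of T cells clustered alone, of automatic doublet calls and of the gate without thinning were chosen only after the result was seen. The difference in CD8 T-like share, 19.6 points, became 25.3 with the looser filter, 9.25 with the stricter one and 21.4 with doublets kept. The difference in virtual memory-like share, -9.23 points, reversed to 1.74 with the looser filter, 2.11 with automatic doublet calls, 2.65 at resolution 0.5, 1.14 with cells thinned before clustering and 1.03 with T cells clustered alone and the low-depth cluster kept. It moved to -14.8 with the stricter filter, -5.81 with genes centred, -13.0 at resolution 2, -0.777 with lists kept in, -0.102 with T cells alone, and -0.318 and -3.59 with the gate, thinned and not. Of the 24 genes named in virtual memory-like cells, 7 would still be named from a minimum of 10 CPM and 0 without a minimum, and of the 10 in naive-like cells 5 and 0. Log2 ratios not taken relative to the median reversed for S100a4 with T cells alone (-0.17) and in cluster 5 for Ccl5 (-0.52) and Ctla2a (-0.46), where S100a4 had 0 UMIs labelled IL-4 knockout and no value. The difference in macrophage-like share, -13.9 points, ran from -17.6 with the looser filter to -4.49 with the stricter one over 8 settings. Among lists at the outer percentiles, medians reversed for NK receptors in cluster 6 (-0.00905) and for the type I interferon response in virtual memory-like cluster 5 (-0.0366) and naive-like cluster 2 (-0.28). Lists nearer 0 changed sign too, such as the interferon gamma response in virtual memory-like cells, -0.16 in the class and 0.11 with T cells alone, or the IL-4 and STAT6 list, 0.10 and -0.22 after thinning. None of the 10 genes named by size in naive-like cells reversed, nor of the 10 in virtual memory-like against naive-like cells, but Itga4 and Cxcr3 turned within naive-like clusters, and Il2rb (0.21) and Cxcr3 (0.44) in virtual memory-like cluster 6 (-0.77 and -0.40).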

Other observations

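The tests of the chromosome segment around Il4, of each non-T class by itself and of T cells clustered alone were chosen only after the result was seen.

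Cluster 7, led by the chemokine Xcl1 and the costimulatory receptor Tnfrsf9 with Nr4a1 and Eomes, held 2.61% of kept cells labelled control and 4.71% of those labelled IL-4 knockout. Cluster 12, led by Lgals1, Ikzf2, Izumo1r and Myb, held 2.10% and 0.269%. Neither took a name from the markers. With CD8 T-like cells clustered alone, an antigen-experienced-like cluster with S100a4, S100a6 and Itgb1 held 69 and 205 cells.

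Genes such as Samd9l, Fosb, Junb, Lars2 and Trim56 differed in the same direction in naive-like and virtual memory-like cells. A difference of the whole library, such as handling or RNA quality, could account for part of them, as in pooled B-like, macrophage-like and type 1 dendritic-like cells their median log2 ratio, signed by the direction in clusters 0 to 3, was 0.68 against 0.76 in clusters 0 to 3. It was 0.72 in B-like cells and 0.60 in dendritic clusters 8 and 15 but 0.36 in macrophage-like cells, less than the prediction asked for. The pool had a different make-up in each library (1420 of 2104 and 129 of 505 cells macrophage-like). In it 82 of 88 genes kept their direction, but Cd55 stood at 1.01 against -1.14 in clusters 0 to 3. Fosb (0.94 in the pool against 2.17), Fos (0.84 against 1.98) and Junb (0.74 against 1.70) fell short too and went both ways by class, with 0.71, 0.79 and 1.13 in B-like cells, -0.23, -0.21 and 0.15 in dendritic clusters 8 and 15 and 0.55, 1.02 and -0.40 in macrophage-like cells, so for these genes it stays open. Of these genes, 3.37% (0.701 to 9.54) lie within 20 Mb of Il4, against 2.57% of all genes, so a donor chromosome segment there does not hold most of them. The test of that segment decides no more, since only 48 of 1867 genes lie there and the share it asked for could hardly be reached. Effects of such a segment on the genes inside it, or through them on others, stay open. A few genes taking much of the counts was not put to a test that decides, since leaving Gm42418, ribosomal protein and mitochondrial genes out of the totals (94.4% past the 1.5-fold size in naive-like cells) shifts every gene by 1 factor.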
